A study of Homo sapiens with 6 samples.

How the data were processed

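The 6 libraries are streptavidin pull-downs of RNA from IMR90 cells, prepared with a stranded total RNA kit with UMIs, per the labels' protocols. Labelling used 500 µM biotinyl-tyramide and 1 mM H2O2 for 1 minute. The design text and the molecule label of the series speak of genomic DNA and of another assay, while the title and protocols describe the RNA assay used here. The deposited table holds whole-number UMI counts per gene for 62754 genes, not normalized. Per the submitters' processing notes, bcl2fastq 2.20 and FastQC were used with the build GRCh38. The aligner, counter and annotation are not given in the sources used here, nor is whether counting used strand, so antisense and overlapping genes are uncertain.

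Of the genes, 20393 carry no symbol in the table, and these were not named in the text. Of the 42361 with a symbol, 40844 (96.4%) matched the RefSeq gene table of GRCh38 by symbol or synonym, from which the coordinates come. Groups came from the titles, with 1 library in each of 6 groups. The labels give no separate cultures per group, so p-values measure the spread between these libraries over the model.

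Counts were tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test with TMM scaling, on 11647 genes kept by filterByExpr with a minimum count of 10. All 6 libraries entered 1 model with a term for each pair of H2O2 and control library and a term for H2O2, which leaves 2 residual degrees of freedom. The contrasts were H2O2 against control, ICM SRSF7 against Prol SRSF7 and Prol SRSF7 against Prol NLS, with Benjamini-Hochberg adjustment and a threshold of 0.05. The model thus treats the labelled and the unlabelled library of a pair as 2 readings of its culture. The common coefficient of biological variation was 0.658. The SE given with a log2 change is the size of that change divided by the square root of the test's F statistic. It is thus derived from the test and is not a separate estimate of error. Gene lists were tested with camera of limma 3.58.1, with a preset correlation of 0.01 and with an estimated one, over 78 tests (26 lists in 3 contrasts).

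Single libraries were compared by 9 log2 ratios of CPM on the TMM scale, with a pseudocount of 0.5, over genes with a mean of at least 10 UMIs. For each ratio an exact 95% interval was taken from the counts (for a ratio of ratios, from the summed counting variances). It covers counting error only. A gene was counted as higher or lower where the ratio was at least 2-fold and its interval excluded 0 on the log2 scale. No test of conditions is possible on such ratios. A list's median was set against 10000 random lists matched in 20 expression bins, as a description of these libraries. Floors correspond to 3 UMIs. TMM and total UMIs give different centres where a library's make-up stands apart: the median gene's ICM H2O2 over control ratio was -0.68 with TMM and -1.88 with total UMIs, and its ICM over Prol ratio among labelled libraries -0.74 and -1.59.

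On simulated counts at the dispersion of these data, 0.433, edgeR recovered 1% of genes changed 4-fold and 6.1% of those changed 8-fold in the H2O2 contrast. It recovered none of either size in the ICM contrast, and none and 1% in the SRSF7 against NLS contrast. At a dispersion of 0.1 it recovered 78%, 69% and 58% of genes changed 4-fold. The ratio rule recovered from 52.2% to 100% of genes changed 4-fold, with 161 to 671 false calls from counting noise, and the intervals held the true ratio in 94.9% to 97.8% of genes.

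The design, the 31 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took, in each direction, the 10 genes with the smallest p among those called in an edgeR contrast, or with the interval bound farthest from 0 in a ratio. It left out XIST, Y-linked genes, genes without a symbol, clone names and symbols ending in P and a number, which also drops a few true genes of that form. It then added 18 genes fixed by name and up to 4 members with the most UMIs of each list. The text gives a part of these. Alternatives were other size factors, total UMIs, total UMIs without mitochondrial, ribosomal and small structured RNAs, DESeq2 1.42.0, no count filter, no pair term, fits on 4 libraries, each pair left out, other minimum counts (25 and 5) and a pseudocount of 2. Fits without the ICM SRSF7 H2O2 or the Prol NLS H2O2 library were chosen after seeing the data. The other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.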

Results

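RNA close to a tagged protein was measured in IMR90 cells, a line of human lung fibroblasts, by APEX labelling. APEX is an engineered peroxidase that, given biotinyl-tyramide and H2O2, attaches biotin to molecules within a short distance, and the biotin-bearing RNA is then pulled down with streptavidin. In 4 of the 6 libraries the tagged protein was SRSF7, a splicing factor of the SR family, and in 2 it was the construct labelled NLS. Each measured combination of tag and state had an H2O2 library, in which labelling was switched on for 1 minute, and a control library without H2O2. The labels do not say whether the libraries of a pair came from the same culture. The cells were proliferating (Prol) or had been treated for 6 days with the agent labelled ICM, which the design uses to induce a senescent state. The NLS construct was measured in proliferating cells only, so no NLS library with ICM exists here. Each of the 6 groups held 1 library, so no value below has a replicate of its own. Intervals in brackets are 95% intervals that cover counting error only.

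Depth differed widely between the libraries. The Prol NLS H2O2 library held 112917 UMIs (unique molecular identifiers, each counting 1 captured molecule) and its control 764790. The Prol SRSF7 pair held 4477351 UMIs with H2O2 and 3882450 without. The ICM SRSF7 pair held 589388 with H2O2 and 7838340 without. In 2 of the 3 pairs the labelled library was thus the shallower one. The ICM SRSF7 H2O2 library also stood apart in make-up: its 10 most abundant genes took 34.2% of its UMIs (exact binomial interval 34.1 to 34.3), against 6.20% to 11.5% in the other libraries. HSP90AA1, an HSP90 chaperone gene, took 11.9% and the nuclear long non-coding RNA MALAT1 10.6%.

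**Figure D1:**
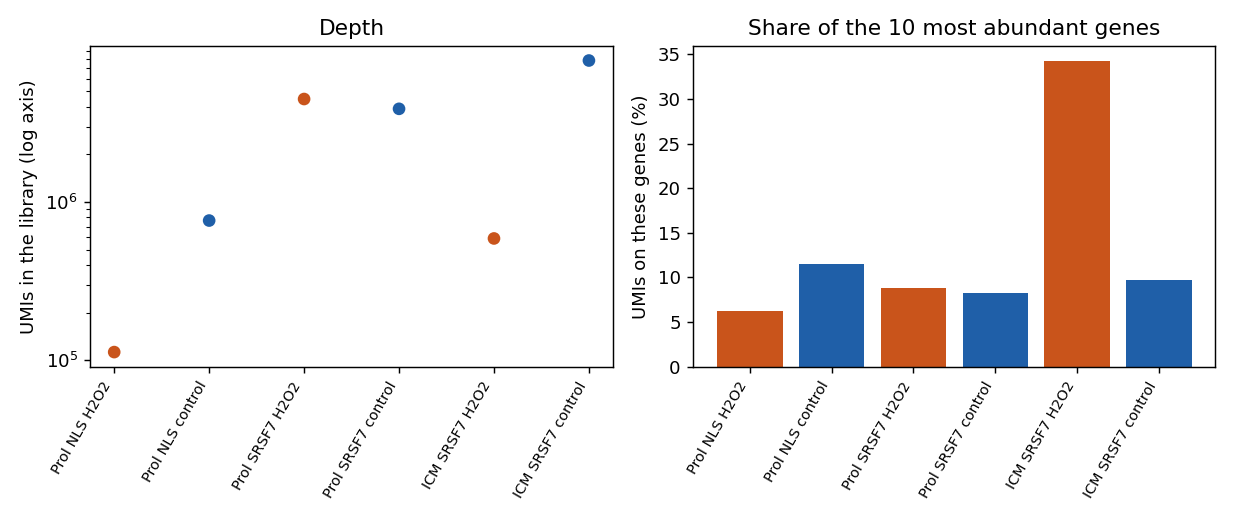
Left, UMIs per library on a log axis; right, the percentage of UMIs on the 10 most abundant genes of each library; orange marks H2O2 libraries and blue control libraries. Depth runs from 112917 to 7838340 UMIs, and the ICM SRSF7 H2O2 library has the largest share on 10 genes, 34.2%.

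SRSF7 itself was read at a low level in all libraries. On the TMM scale it ran from 54.9 CPM in the Prol NLS control to 101 in the Prol NLS H2O2 library, the latter from 14 UMIs. As a share of all UMIs it ran from 0.0041% in the ICM SRSF7 H2O2 library to 0.0124% in the Prol NLS H2O2 library. RN7SK, the 7SK RNA of transcriptional elongation control, had 0 UMIs in each of the 6 libraries. Whether the counting covered this gene is not given in the sources used here, so the zeros set no limit on its level.

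The comparison of ICM with proliferating cells asks which RNAs differ between the states, over the 4 SRSF7 libraries. Each state enters as the average of its labelled and its unlabelled library. The contrast thus cannot tell the ICM state from other differences between the pairs. Its p-values measure the spread between these libraries over the model, not between cultures. The genes that fell included single genes of the cell cycle, of contractile fibres and of the extracellular matrix. The proliferation marker MKI67 (ENSG00000148773, chromosome 10, 128096659 to 128126423, GRCh38) fell by 6.83 on the log2 scale (SE 1.29, edgeR adjusted p = 0.000492), with 842 and 676 UMIs in the proliferating libraries and 0 and 24 in the ICM libraries. The linker histone gene H1-5 (chromosome 6, 27866792 to 27867588) fell by 9.34 (SE 1.77, edgeR adjusted p = 0.000492), from 170 and 376 UMIs to 0 and 1. ACTG2 and CNN1, genes of smooth muscle actin and calponin, fell by 6.84 (SE 1.32) and 7.27 (SE 1.42). The collagen gene COL4A1 (chromosome 13, 110148963 to 110307157) fell by 6.55 (SE 1.38, edgeR adjusted p = 0.00211). Its CPM went from 1473 to 2.91 among the labelled libraries, the latter from 1 UMI, and from 836 to 36.5 among the unlabelled ones.

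Further genes that fell included TNC, which codes for the matrix protein tenascin C, with a log2 change of -5.70 (SE 1.16), and PLAU, the urokinase gene, with -6.12 (SE 1.28). Both had 0 UMIs in the ICM SRSF7 H2O2 library. Its control had 146 and 291, against 1168 and 2639 in the Prol SRSF7 control. TGM2, a transglutaminase that cross-links proteins, changed by -5.79 (SE 1.21), MXRA8 by -5.48 (SE 1.16) and the imprinted gene MEST by -6.99 (SE 1.44). The long non-coding RNA LUCAT1 (ENSG00000248323, chromosome 5, 91302986 to 91314402) rose by 6.37 on the log2 scale (SE 1.15, edgeR adjusted p = 0.00037). It had 23 and 6 UMIs in the proliferating libraries against 136 and 1359 with ICM. TAF3, a subunit of the general transcription factor TFIID, rose by 5.49 (SE 1.43, edgeR adjusted p = 0.0247), and SNAPC1, a subunit of the complex that starts snRNA transcription, by 3.87 (SE 1.09, edgeR adjusted p = 0.0474). For TAF3 the rise was larger among the labelled libraries, from 35.3 to 3910 CPM, than among the unlabelled ones, from 23.6 to 124.

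Of 11647 genes tested, edgeR's quasi-likelihood test called 4 higher and 92 lower with ICM at an adjusted p under 0.05, the fourth higher gene having no symbol in the table. Without the ICM SRSF7 H2O2 library, chosen after seeing the data, 1 gene was called in each direction, with 1 ICM library left in the fit. DESeq2 called 79 higher and 301 lower, and scaling by total UMIs left 1 and 23.

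By gene list, 11 of the 42 tested extracellular matrix genes fell and none rose, and 34 were lower when adjusted over the list alone. Their median log2 change was -3.51, against -0.27 for the other genes (camera adjusted p = 5.64e-35 with a preset correlation, adjusted p = 0.598 with an estimated correlation). Among 24 fibroblast cytoskeleton genes 5 fell, 14 adjusted over the list alone, with a median of -3.09. Of 49 replication-dependent histone genes 5 fell, 20 adjusted over the list alone, with a median of -4.01. Of 44 proliferation genes 4 fell, 17 adjusted over the list alone, with a median of -3.0. For these 3 lists too the adjusted p was 0.598 with an estimated correlation. Without the ICM SRSF7 H2O2 library the list medians were -3.62 for matrix, -3.99 for cytoskeleton, -3.66 for histone and -3.25 for proliferation genes, with 1 histone gene and no gene of the other 3 lists called.

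Of 25 tested genes known to be secreted by senescent fibroblasts, 3 fell and none rose, and adjusted over the list alone 10 were lower and 1 higher, with a median of -2.62. The members with the most UMIs were IGFBP5 and IGFBP4, which bind insulin-like growth factors, and PLAU, which is also a named gene above. Of the 13 mitochondrially encoded mRNAs 2 fell, 10 adjusted over the list alone, with a median of -3.15. Ribosomal protein genes had a median of -1.52 over 83 genes, with none called. Each of these 3 lists had a camera adjusted p = 0.598 with an estimated correlation.

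Other lists had medians above 0 and no gene called over all genes tested. The median was 1.05 for 30 cell cycle inhibitors and p53 targets, of which 2 were higher adjusted over the list alone, and 1.02 for 36 oxidative stress and heat shock genes, of which 3 were higher and 1 lower adjusted over the list alone. It was 0.98 for 32 genes of speckle proteins and SR kinases and 0.35 for 39 core spliceosome protein genes. Without the ICM SRSF7 H2O2 library these medians were 0.84 for the inhibitors and p53 targets, 1.085 for the stress genes, 0.40 for the speckle list and 0.059 for the core spliceosome. The preset camera test placed all 4 above the other genes, and with an estimated correlation the adjusted p was 0.598 for each.

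Between the 2 unlabelled SRSF7 libraries, the deepest comparison of the states, the antioxidant enzyme gene HMOX1 was 6.61 higher with ICM on the log2 scale (5.80 to 7.74), from 10 to 2587 UMIs. OSGIN1, an oxidative stress response gene, was 3.77 higher (3.31 to 4.32), and DDIT3, a transcription factor of the stress response, 3.88 higher (3.43 to 4.40). CDKN1A, which codes for the cell cycle inhibitor p21, was 2.68 higher and its fellow p53 target MDM2 2.06 higher; among the labelled libraries their log2 ratios were -0.335 (-0.559 to -0.126) and 0.57 (0.22 to 0.88), and -1.185 and -0.283 when scaled by total UMIs, which changes the sign for MDM2. The iron storage genes FTH1 and FTL were 2.45 and 1.89 higher. TAGLN, a smooth muscle actin-binding gene, was 6.16 lower (log2 ratio -6.16, -6.35 to -5.98), fibronectin (FN1) had a log2 ratio of -4.89, and COL1A1 of -2.83.

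In that unlabelled comparison all 43 matrix genes, 23 of 24 cytoskeleton genes and 41 of 45 proliferation genes were at least 2-fold lower with ICM. The medians were -2.89, -3.25 and -3.23, each at percentile 0 of 10000 random lists of matched expression. Cell cycle inhibitors and p53 targets had a median of 1.13 (percentile 100) with 17 of 30 at least 2-fold higher, and oxidative stress and heat shock genes 0.96 (percentile 100) with 18 of 36. Spliceosomal snRNAs were lower, with a median of -2.46 and 16 of 17 at least 2-fold lower, as were snoRNAs at -2.04. Scaled by total UMIs, these lists kept their signs, with -2.57 for the matrix and -2.13 for the snRNAs. CDKN2A, the p16 gene, had a log2 ratio of -2.04 among the unlabelled libraries and of 0.79 (-0.13 to 1.53) among the labelled ones, the latter changing sign to -0.057 when scaled by total UMIs. Lamin B1 (LMNB1), known to fall in senescence, had -3.29 and -0.22, the latter with an interval from -1.805 to 0.845 and 6 UMIs in the ICM library.

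Between the 2 labelled SRSF7 libraries, matrix genes again had a low median, -3.98, with 42 of 43 at least 2-fold lower, and cytoskeleton genes -3.96. FN1 had a log2 ratio of -6.57 (-7.17 to -6.07) and vimentin (VIM) of -7.54. HSP90AA1 was 6.19 higher (6.16 to 6.21), MALAT1 4.66 and the translation initiation gene EIF3J 6.97 (6.78 to 7.17). Genes of speckle proteins and SR kinases had a median of 1.40 (percentile 98.1) with 18 of 31 at least 2-fold higher, among them RBM25 at 4.69 and DDX5 at 2.18. Scaled by total UMIs that median was 0.55. Over the 11164 genes read in both, the labelled and unlabelled ICM ratios correlated across genes at r = 0.406, where genes are not independent replicates. They shared 597 higher genes against 322.3 for independent lists, and 1331 lower genes against 755.1.

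**Figure D2:**
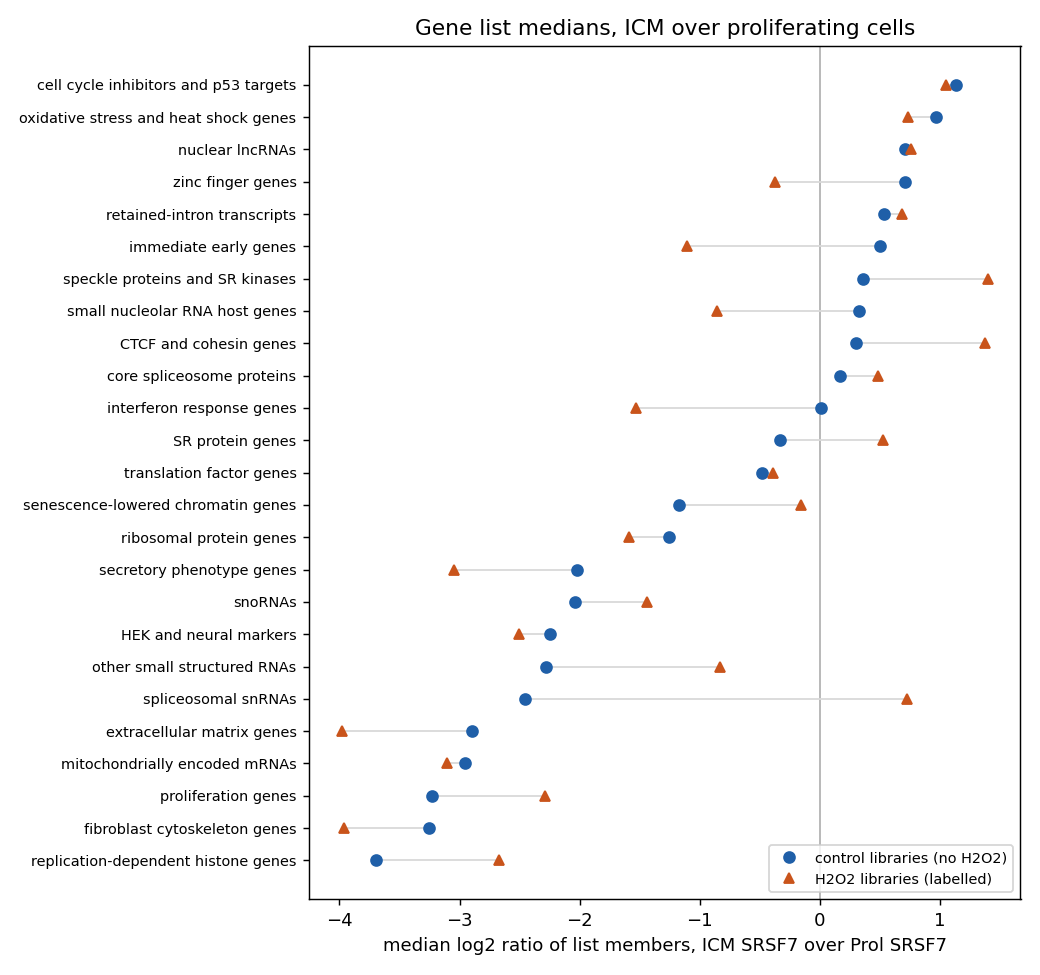
Median log2 ratio of ICM SRSF7 over Prol SRSF7 for each gene list; blue circles compare the control libraries and orange triangles the H2O2 libraries, 1 library per group. Matrix, cytoskeleton and proliferation genes lie below -2 in both, and spliceosomal snRNAs lie at -2.46 in the control and 0.72 in the H2O2 libraries, the latter changing to -0.126 when scaled by total UMIs.

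CTCF, whose protein organises chromatin loops, was 1.49 higher with ICM on the log2 scale among the unlabelled libraries, from 127 to 904 UMIs, and 2.72 higher among the labelled ones, from 163 to 78 UMIs in a shallower library. The paraspeckle RNA NEAT1 was 2.17 and 2.74 higher in these comparisons. SON and SRRM2, the core proteins of nuclear speckles, had log2 ratios of 1.23 and 1.61 among the unlabelled libraries and of 0.97 and -0.51 among the labelled ones. SR protein genes had medians of -0.33 and 0.52, and the list changed sign to -0.33 among the labelled libraries when scaled by total UMIs.

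In all, 2886 genes were at least 2-fold higher and 2660 lower with ICM among the unlabelled libraries, and 4324 and 1939 when scaled by total UMIs. Among the labelled libraries 2180 were higher and 3575 lower, and 1236 and 5936 when scaled by total UMIs. These counts describe 2 libraries at a time and carry no test of the conditions.

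**Figure D3:**
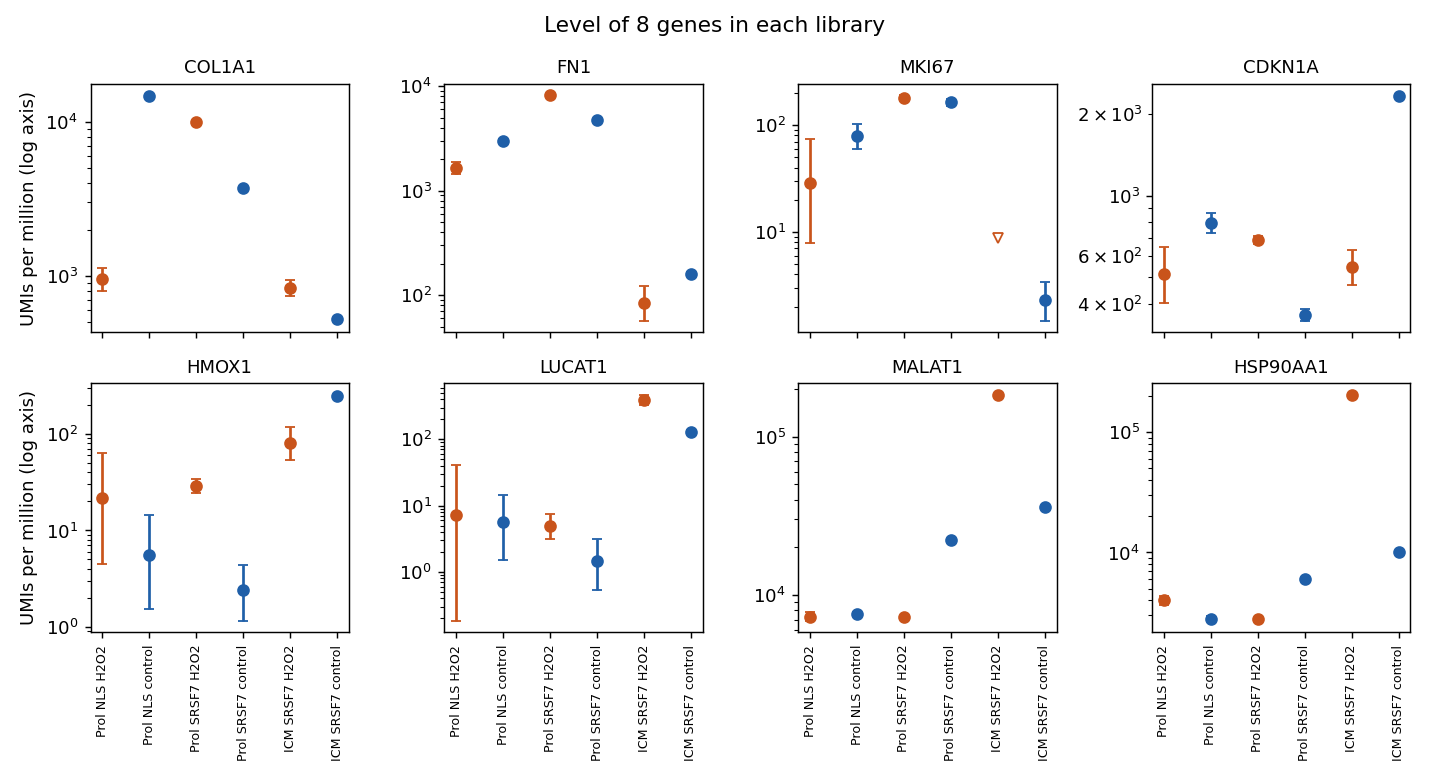
CPM (log axis) of 8 genes in each of the 6 libraries; orange marks H2O2 and blue control libraries, bars are 95% Poisson intervals, and an open triangle marks a library with 0 UMIs at the level of 3 UMIs. COL1A1, FN1 and MKI67 are lower in both ICM than in both Prol SRSF7 libraries, and LUCAT1 and HMOX1 are higher.

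The H2O2 over control comparison is meant to ask which RNAs are labelled near the tagged protein. With 1 library per group, its ratios cannot tell labelling from other differences between the libraries of a pair. A higher ratio is thus not by itself evidence of nearness to the tagged protein. In proliferating SRSF7 cells, the pair with the most even depth, mitochondrially encoded mRNAs were higher with H2O2, with a median log2 ratio of 1.45 (percentile 100) and MT-ND5 at 1.86 (1.79 to 1.92). HMOX1 was 3.52 higher (2.66 to 4.68), from 10 to 136 UMIs, and COL1A1 1.43 higher. Small nuclear and nucleolar RNAs were lower: SNORD3A, a U3 RNA, had a log2 ratio of -3.29 (-3.53 to -3.06), the U4 RNA RNU4-2 of -2.88 (-3.02 to -2.74), and the signal recognition particle RNA RN7SL1 of -2.02. Spliceosomal snRNAs had a median of -1.42 and snoRNAs of -1.09, both at percentile 0, and MALAT1 had a log2 ratio of -1.61 (-1.63 to -1.59). Genes of speckle proteins and SR kinases had a median of -0.36 (percentile 0.03), with SRRM2 at 1.57 and RBM25 at -0.66. Near-identical copies among the small RNA genes make their single values uncertain. In this pair 572 genes were at least 2-fold higher and 550 lower of 12406.

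In ICM SRSF7 cells, the H2O2 library was higher than its control in transcripts of acidic nuclear proteins. PTMS, which codes for parathymosin, was 7.01 higher on the log2 scale (6.84 to 7.18), ANP32B 6.65 (6.57 to 6.73) and the nucleosome-binding gene HMGN5 6.74 (6.59 to 6.89). SELE, FBN3 and SIRPB2 had larger ratios on few UMIs, with 42, 23 and 22 against 0 in the control. HSP90AA1 was 4.33 higher and MALAT1 2.34 (2.33 to 2.35). Spliceosomal snRNAs had a median of 1.80 (percentile 100) and genes of the matrix -1.17 (percentile 0.04). As shares of all UMIs, from control to H2O2, the snRNAs went from 0.0158% to 0.0232% and the matrix genes from 0.609% to 0.288%. CDKN1A had a log2 ratio of -2.09. By count 1986 genes were at least 2-fold higher and 3037 lower of 13314, and 735 and 7063 when scaled by total UMIs.

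In proliferating NLS cells COL1A1 had a log2 ratio of H2O2 over control of -3.94 (-4.21 to -3.70), COL5A1 of -3.82 and RN7SL1 of -2.68. Matrix genes had a median of -1.53 (percentile 0.75) and spliceosomal snRNAs of -1.81 (percentile 1.80). Genes higher with H2O2 included H2BC11, a histone gene, at 4.66 (3.83 to 5.69), and FZD4, a WNT receptor gene, at 4.52 (3.20 to 6.37). H2BC11 had 66 UMIs against 13 and FZD4 24 against 5. GRIN3A, DCLK3 and ACOXL were also higher, with 22, 23 and 20 UMIs against 1, 4 and 4. These last genes had at most 2 UMIs in any SRSF7 library. There 997 genes were at least 2-fold higher and 2074 lower of 6929, and 1406 and 1419 when scaled by total UMIs.

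Over the 3 pairs together, edgeR called no gene higher or lower with H2O2 at an adjusted p under 0.05, with 95 genes at an unadjusted p under 0.05, and DESeq2 called none with 240. Mitochondrially encoded mRNAs had the highest list median among the lists called, 1.06, against -0.31 for the other genes (camera adjusted p = 2.99e-09 with a preset correlation, adjusted p = 0.598 with an estimated correlation). The preset test also called matrix genes (median -0.67), snoRNAs (-0.87), fibroblast cytoskeleton genes (-0.59) and spliceosomal snRNAs (-0.33) lower. With an estimated correlation their camera adjusted p lay between 0.670 and 0.723. NFIA was the 1 gene at least 2-fold higher in each pair, where independent pairs would give 7.4, and RNVU1-7 and SNHG7 were the 2 lower ones, where they would give 13.8. NFIA and SNHG7 were named after their values were seen. Simulated at the spread of these data, the test recovered 1% of genes changed 4-fold and 6.1% of those changed 8-fold.

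The SRSF7 against NLS comparison asks how the SRSF7 pair differs from the NLS pair in proliferating cells. Its edgeR contrast averages the labelled and the unlabelled library of each pair. It thus cannot tell what the SRSF7 tag labelled from other differences between the pairs. Genes called lower with SRSF7 included the mitochondrial tRNA genes MT-TT, with a log2 change of -5.69 (SE 1.20), and MT-TQ, with -5.26 (SE 1.13). MT-TT had 237 UMIs in the NLS control but 3 in the NLS H2O2 library, against 17 and 16 in the SRSF7 pair. Among others, the mucin gene MUC16 changed by -10.32 (SE 1.97, edgeR adjusted p = 0.000502), the myeloperoxidase gene MPO by -8.08 (SE 1.69, edgeR adjusted p = 0.00186) and the protocadherin gene PCDHB3 by -7.36 (SE 1.59). MUC16 had 19 and 26 UMIs in the NLS libraries and 1 and 0 in the proliferating SRSF7 libraries. POLG-DT, SLC35G1 and CYB5RL changed by -6.01, -5.47 and -5.42. POLG-DT had 217 UMIs in the NLS control and 5 in the NLS H2O2 library, against 15 and 7 in the SRSF7 pair. edgeR called 64 genes lower and none higher, with 410 at an unadjusted p under 0.05, and DESeq2 called 184 lower and none higher. Scaled by total UMIs none was called, and without a filter on low counts 1 was.

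By list, spliceosomal snRNAs had a median change of -2.24 and snoRNAs of -1.74 with SRSF7, and matrix genes of 1.00 (camera adjusted p = 1.32e-08, 5.12e-09 and 1.73e-05 with a preset correlation). With an estimated correlation the adjusted p was 0.598 for the 2 small RNA lists and 0.674 for the matrix. Markers of other cell types took larger shares in the NLS libraries: leukocyte markers held 0.0283% of the UMIs of the NLS H2O2 library and 0.0084% of its control, against 0.0042% and 0.0024% in the SRSF7 pair. Among the unlabelled libraries GOLGB1, a Golgi coiled-coil gene, was 2.98 higher with SRSF7 (2.76 to 3.22), KTN1 2.62 and the actin regulator ROCK1 2.59. Over 10886 genes the labelled and unlabelled SRSF7 over NLS ratios correlated across genes at r = 0.074, and they shared 250 higher genes against 298.7 for independent lists and 334 lower genes against 242.5, with 477 genes in opposite directions.

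Among the labelled libraries 1870 genes were at least 2-fold higher and 1389 lower with SRSF7, and 1412 and 1666 when scaled by total UMIs. Among the unlabelled ones, where no labelling took place, 1747 were higher and 2520 lower, and 2378 and 2070 when scaled by total UMIs.

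Between tags, the SRSF7 over NLS ratio of H2O2 over control was 5.38 on the log2 scale for COL1A1 (5.13 to 5.62) and 4.68 for the cytoskeletal linker PLEC (4.38 to 4.98). PIEZO1, an ion channel gene, had a larger ratio with a wider interval, 6.32 (4.53 to 8.12), from 2 UMIs in the NLS H2O2 library. In all 1807 genes were higher and 1975 lower, and 1198 and 2713 when scaled by total UMIs. Between states, the ICM over Prol ratio of H2O2 over control was 7.48 for ANP32A (7.25 to 7.71), 6.53 for PTMA, the prothymosin gene, and 3.95 for MALAT1 (3.93 to 3.97). It was -5.09 for HMOX1 (-6.14 to -4.04) and -4.33 for ADAR, an RNA-editing enzyme gene. There 2231 genes were higher and 2445 lower, and 953 and 5835 when scaled by total UMIs. Without an NLS library with ICM, the ratios between states cannot be tied to the SRSF7 tag.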

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

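Of the tests below, those of other cell types, of few UMIs, of HSP90AA1 with ICM, of the 3 explanations for the matrix genes and of other splits were chosen only after the result was seen. The olfactory receptor and acidic protein tests were set out before.

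Some genes and lists moved in opposite directions with H2O2 in 2 pairs, each pair being 1 library against 1, and none of these differences was tested. Over genes read in both pairs, the H2O2 over control ratios correlated at r = -0.262 between Prol NLS and Prol SRSF7, with 37.2% of the same sign. The values were 0.011 and 53.6% between Prol NLS and ICM SRSF7, and -0.129 and 45.6% between Prol SRSF7 and ICM SRSF7. The disagreement was thus not limited to the genes and lists below. The difference in log2 H2O2 over control ratio between Prol SRSF7 and Prol NLS was 5.38 for COL1A1 and 3.0 for SRRM2. Between ICM SRSF7 and Prol SRSF7 it was 3.95 for MALAT1 and 3.22 for the median of spliceosomal snRNAs. Between ICM SRSF7 and Prol NLS it was 3.60 for spliceosomal snRNAs, 3.10 for other small structured RNAs and 2.42 for chromatin genes lowered in senescence. Scaled by total UMIs, the ICM SRSF7 median of the chromatin genes was -0.004 and that of other small structured RNAs -0.194, so the opposite signs of these lists rest on the scaling.

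Over the 3 pairs, 0 genes were called by edgeR for H2O2, and the highest count of the other splits of the 6 libraries into 3 and 3 was also 0, in 10 of 10 splits. With 10 splits no share under 0.05 can be reached.

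Transcripts of acidic nuclear proteins and HSP90AA1 took a large share of the ICM SRSF7 H2O2 library. A further list of 23 genes of such proteins, without those named, had a median log2 ratio over its control of 2.53 (percentile 99.99), with 18 of 23 at least 2-fold higher. Random lists of matched expression had a median of 0.938. A class of transcripts recovered more in that library would give such an excess. The list was not read with total UMIs, where the median gene's ratio was -1.88 against -0.68 with TMM. These 23 genes took 7.47% of the ICM SRSF7 H2O2 library (7.40 to 7.53) and at most 0.753% of the other 2 shallow libraries, the NLS pair. Few UMIs alone thus did not give such a share there, but that pair also differs in tag and state. This test of few UMIs replaced earlier versions on other genes. The median ICM over Prol ratio of the 23 genes among unlabelled libraries was -0.35, which argues against a rise of these 23 with ICM. For HSP90AA1 such a rise stays open, since its ratio there was 0.76, from 0.642% to 1.36% of UMIs, and HSP90B1 went from 0.278% to 0.705%. HSP90AA1 took 11.9% of the ICM SRSF7 H2O2 library, so the rise seen without labelling would cover only part of that share.

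MUC16 and MPO, genes known mainly from other tissues than lung fibroblasts, were called higher in the NLS libraries on few UMIs; no list of such genes was tested among the 64 called. Olfactory receptor genes, silent in fibroblasts, took 1470 CPM of total UMIs in the NLS H2O2 library, 386 in its control and 56.0 in the ICM SRSF7 H2O2 library, also shallow, against at most 22.4 in the 3 deeper libraries. The lowest of the 3 shallow values was 2.5 times the highest deep one. This lay between the bounds set for and against a background such as genomic DNA. That lowest value belongs to the ICM SRSF7 H2O2 library, which is not part of the NLS pattern. In both NLS libraries the share lay well above the deep ones, the direction such a background would give, so that explanation stays open. Cells of another type stay open: the highest share of an epithelial, endothelial, leukocyte or erythroid list in an NLS library was 0.028%, but MUC16 itself held 19 UMIs there, and leukocyte, epithelial and endothelial markers took 0.0283%, 0.0213% and 0.0257% of the NLS H2O2 library against 0.0042%, 0.0008% and 0.0038% of the Prol SRSF7 one. Markers of HEK and neural lines took 0.112% and 0.192% of the NLS libraries and 0.0977% and 0.0991% of the Prol SRSF7 ones.

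Matrix, contractile and proliferation genes were lower with ICM. Among unlabelled libraries, without the ICM SRSF7 H2O2 library, the matrix median was -2.89, which argues against the make-up of that library as the cause. It was -2.57 when scaled by total UMIs, a change that shifts every gene alike. The fall thus does not rest on the choice between these scalings, and other scalings were not tested for it here. A loss of cytoplasmic mRNA stays open: translation factor genes had a median of -0.49 there, but ribosomal protein genes had -1.26, GAPDH had -1.17, and nuclear lncRNAs went from 2.55% to 5.54% of UMIs. The ICM treatment, which the design names, also stays open, with 1 library per group and no test of culture or library differences.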

How the results depend on the processing

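The fits without 1 library were chosen after seeing the data. Among counts of called genes and list tests, 101 of the alternative values stayed within 1.5 times the main one and 35 did not. The cause was not tested.

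ICM against proliferating, with 4 genes higher and 92 lower, gave 11 higher with DESeq2's size factors, 1 and 23 with total UMIs, 79 and 301 with DESeq2, 40 lower with no filter, 8 higher with the 4 SRSF7 libraries alone, and 1 and 1 without the ICM SRSF7 H2O2 library. SRSF7 against NLS, with 64 lower, gave 0 with total UMIs, 1 with no filter, 184 with DESeq2 and 444 with the 4 proliferating libraries alone. The H2O2 contrast gave 0 genes in either direction under each alternative run, leaving out each pair included (0 to 0). Of the 30 list tests called, 0 held with an estimated correlation.

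For the ratios, total UMIs and total UMIs without mitochondrial, ribosomal and small structured RNAs gave, for H2O2 over control in ICM SRSF7, 735 and 737 higher and 7063 and 7056 lower. For ICM over Prol among labelled libraries they gave 1236 and 1201 higher and 5936 and 6018 lower. For the ICM over Prol ratio of ratios they gave 953 and 951 higher and 5835 and 5861 lower, and for the SRSF7 over NLS one total UMIs gave 1198 higher. A minimum of 25 UMIs gave 308 higher and 1341 lower in the Prol NLS pair, 342 lower in the Prol SRSF7 pair, and 894 and 1658 lower for SRSF7 over NLS among labelled and unlabelled libraries. A minimum of 5 gave 1842 higher in the Prol NLS pair. A pseudocount of 2 gave 1367 lower for the ICM over Prol ratio of ratios and 1035 higher for the SRSF7 over NLS one.

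Of the list medians outside the central 95% of random lists, those that changed sign under the 2 totals were, for H2O2 over control in Prol NLS, ribosomal protein genes (0.372 and 0.327) and zinc finger genes (0.358 and 0.313). For ICM SRSF7 they were snoRNAs (-0.956 and -0.953) and chromatin genes lowered in senescence (-0.004 and -0.001), and of the genes fixed by name that were at least 2-fold higher or lower, HMGB1 changed sign (-0.081 and -0.077). Among those under 2-fold, NEAT1 and COL1A1 changed sign too (-0.474 and -0.517 with total UMIs), as did SON (-1.031) and SRSF7 (-1.119). For ICM over Prol among labelled libraries they were spliceosomal snRNAs (-0.126 and -0.167), and for its ratio of ratios scaRNAs (-0.08 and -0.087) and proliferation genes (-0.485 and -0.493). With a minimum of 25 UMIs they were ribosomal protein genes in Prol NLS (0.068) and zinc finger genes for ICM over Prol (0.008) and SRSF7 over NLS (0.232) among labelled libraries and for the SRSF7 over NLS ratio of ratios (0.114). The depth of the NLS H2O2 library, 112917 UMIs, limits each ratio that uses it.

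Without the term for pairs, edgeR called 0 genes in the H2O2 contrast, with 138 at an unadjusted p under 0.05, against 0 and 95 with it, and DESeq2 called 0 with 240.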

Other observations

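The coiled-coil test below was set out before its result was seen.

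Immediate early genes, known to be induced within minutes of a stimulus, had a median log2 H2O2 over control ratio of 0.49 in Prol SRSF7 (percentile 99.98), with FOSL1 at 1.34, and of -1.92 in Prol NLS (percentile 0.46), with FOSL1 at -2.38. Interferon response genes had a median of 0.006 for ICM over Prol among unlabelled libraries (percentile 31.5). CTCF and cohesin genes had medians of 0.30 and 1.37 for ICM over Prol among unlabelled and labelled libraries (percentiles 86.5 and 93.5), with SMC3 at -0.59 and 2.71. Markers of HEK and neural lines, some of which fibroblasts also express, took 0.0977% to 0.192% of the UMIs of the 4 proliferating libraries and 0.0161% and 0.0345% of the ICM ones.

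Several genes of coiled-coil proteins, such as GOLGB1 and KTN1, were higher in the unlabelled SRSF7 than in the unlabelled NLS library of proliferating cells. A further list of 30 coiled-coil genes, without those named, had a median log2 ratio of 1.46 there (percentile 100), with 17 at least 2-fold higher and 1 lower. In the Prol SRSF7 pair their median H2O2 over control ratio was -0.58 (percentile 0). A property that these transcripts share may thus bear on recovery without labelling. No sequence was given to test base composition, and the unlabelled libraries differ in depth, tag and culture at once.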
